A study of Mus musculus with 18 samples.

How the data were processed

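Gene expression was measured in mouse G1E-ER4 cells on 18 Affymetrix GeneChip arrays, 3 for each of 6 times in 20 nM estradiol (0, 3, 7, 14, 21 and 30 h). Per the labels' protocols, total RNA was extracted with Trizol and labelled with biotin. The labels call the 3 arrays of a time point biological replicates but do not say that they came from separate cultures, so p-values measure the spread between these samples, which may in part be technical. Scan dates and batches are not given in the sources used here.

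The authors deposited log2 expression values, 1 per probe set and array, for 45101 probe sets, 64 of them Affymetrix controls. The log base was read from the values: the highest, 14.4, lies above what a natural or base-10 logarithm of a 16-bit scanner signal can reach. Array medians lay between 4.04 and 4.09, so the deposited values had already been brought to a common scale. The method of summarising probes, of background correction and of scaling between arrays is not given in the sources used here. A scaling that equalises arrays sets the middle of all genes to about the same level at each time, so every change is relative to that middle, and compression of low signals by an unknown background step would make folds of dim genes too small. No detection calls were analysed here.

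Genes were named through the platform annotation paired with the probe sets. It lists 34958 probe sets with 1 gene, 932 with several and no gene for 9211. Entrez identifiers of 34754 of the 1-gene probe sets were found in a RefSeq gene table, which changed no symbol (0). Probe sets with several genes or none were kept out of the gene counts, and no gene was named from them. Of several probe sets for a gene, that with the highest mean over all arrays was used. A gene was tested if it lay above its array's 40th percentile on at least 3 arrays, which left 12727 of 18194 genes. Of 147 genes named by the fixed rule, 71 have more than 1 tested probe set, and only Map1a has probe sets called in opposite directions at 30 h.

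All 18 arrays were fitted together with limma 3.58.1 in R 4.3.3, with a mean per time point and 12 residual degrees of freedom. Each time was compared with 0 h and with the time before it, and an F test asked which genes changed over time. Tests were two-sided, with Benjamini-Hochberg adjustment over the 12727 genes for each comparison, and a gene was called at an adjusted p under 0.05. No pseudocount was needed on values already on a log scale. The number of arrays limits the precision: with 3 per group, n = 3 behind each mean and SD in the text. On data simulated for 12727 genes at 30 h versus 0 h, with 200 genes changed, calls recovered 28% of changes of 1.25-fold, 84% of 1.5-fold, 98% of 2-fold and 100% of 4-fold, with 9 calls among unchanged genes. The same code, tested on simulated data for the other 8 comparisons, recovered 14% to 34% of 1.25-fold, 82% to 88% of 1.5-fold, 96% to 100% of 2-fold and 100% of 4-fold changes, with 3 to 12 calls among unchanged genes. The real comparisons called 14.9% to 69.5% of genes, a far larger share than the 200 changed in the simulation. Because the adjustment depends on that share, the simulated recovery may understate that in the real data. A list shifted by 0.5 in simulated data was called by all 3 list methods, with 0 other lists called. Simulated genes varied independently of each other, so this says nothing about false list calls where genes vary together.

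Gene lists, 25 in all with 436 genes, were fixed beforehand, from textbook knowledge of red cell formation, other blood cell types, the cell cycle and stress. Each list with at least 4 measured genes was tested against all other genes by camera with its preset correlation, adjusted over the lists, and again by camera with an estimated correlation and by fry, which does not compare a list with other genes. Named genes followed a rule fixed at the same stage. It takes the 12 largest rises and falls at 30 h, 8 of each at 3 h and 4 of each between neighbouring times, among called genes whose 3 arrays do not overlap those of the other time. It adds up to 4 members of each list with the largest change at 30 h and 8 genes followed at every time. Unnamed transcripts were skipped. Other genes in the text were singled out after their values were seen, and come from the fixed lists or from gene families chosen later.

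The alternatives fixed before the data were examined were quantile normalization, a shift to equal medians, no filter and a 60th-percentile filter, the mean of a gene's probe sets, every probe set on its own, leaving out probe sets with _x_at or _s_at names, only the arrays of the times compared, a trended and robust variance, the replicate number as a block, a 2-fold minimum and leaving out each array. Added after seeing the data was a shift of each array to the same mean of its bacterial and phage hybridisation controls. The replicate numbers were not used to pair arrays. No 2 arrays held identical values (0 pairs).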

Results

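G1E-ER4 cells are mouse erythroid progenitor-like cells in which the Gata1 gene was disrupted and GATA1 is supplied as a fusion to an estrogen receptor domain, so that estradiol switches the transcription factor on. The study asked how the transcriptome changes as these cells mature toward red cells. Expression was read on 18 arrays, 3 at each of 0, 3, 7, 14, 21 and 30 h in 20 nM estradiol. Arrays of a time point correlated with each other at a mean r of 0.996 to 0.998 across probe sets, and the correlation between 0 h and 30 h arrays was 0.931. No arrays of cells kept without estradiol for the same hours were part of the series analysed here, so estradiol, GATA1 activity and time in culture changed together.

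Gata1 itself was read first. Its probe set lay between 10.15 and 10.30 on the log2 scale on the 3 arrays at 0 h, dropped to a mean of 9.69 ± 0.018 (SD, n = 3) at 3 h and reached 11.08 ± 0.020 at 30 h. The change was -0.52 at 3 h (SE 0.081, limma adjusted p = 0.000214) and 0.87 at 30 h (adjusted p = 7.74e-08). With scaling on the arrays' hybridisation controls, an alternative added after the data were seen, the 3 h changes of Gata1 and Klf1 were not called (adjusted p = 0.181 and 0.262), though at -0.43 and 0.39 they stayed about as large. Where this probe set lies relative to the disrupted part and the fusion is not given in the sources used here, so it checks nothing about the labels. Gata2, the related factor of early progenitors, fell at every time, with log2 changes of -1.02 at 3 h and -4.10 at 30 h, or 17.2-fold (SE 0.062, adjusted p = 3.41e-17). Kit, the stem cell factor receptor, changed by -0.21 at 3 h (adjusted p = 0.253, or 0.0327 with only the arrays of these times fitted), or -0.40 with the mean of its probe sets (adjusted p = 0.00223), and was 27.4-fold lower at 30 h (log2 -4.77, SE 0.13). Myc, a driver of proliferation, fell by 0.78 at 3 h and by 3.18 at 30 h. Zfpm1, the GATA1 cofactor FOG1, rose from 9.93 ± 0.15 to 11.74 ± 0.077, a gain of 1.81. Klf1, an erythroid transcription factor, rose by 0.30 at 3 h and by 0.80 at 30 h. Alas2, the erythroid enzyme that starts heme synthesis, rose by 0.80 at 3 h, 2.26 at 7 h, 4.15 at 14 h, 5.65 at 21 h and 6.49 at 30 h, or 90.0-fold.

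**Figure D1:**
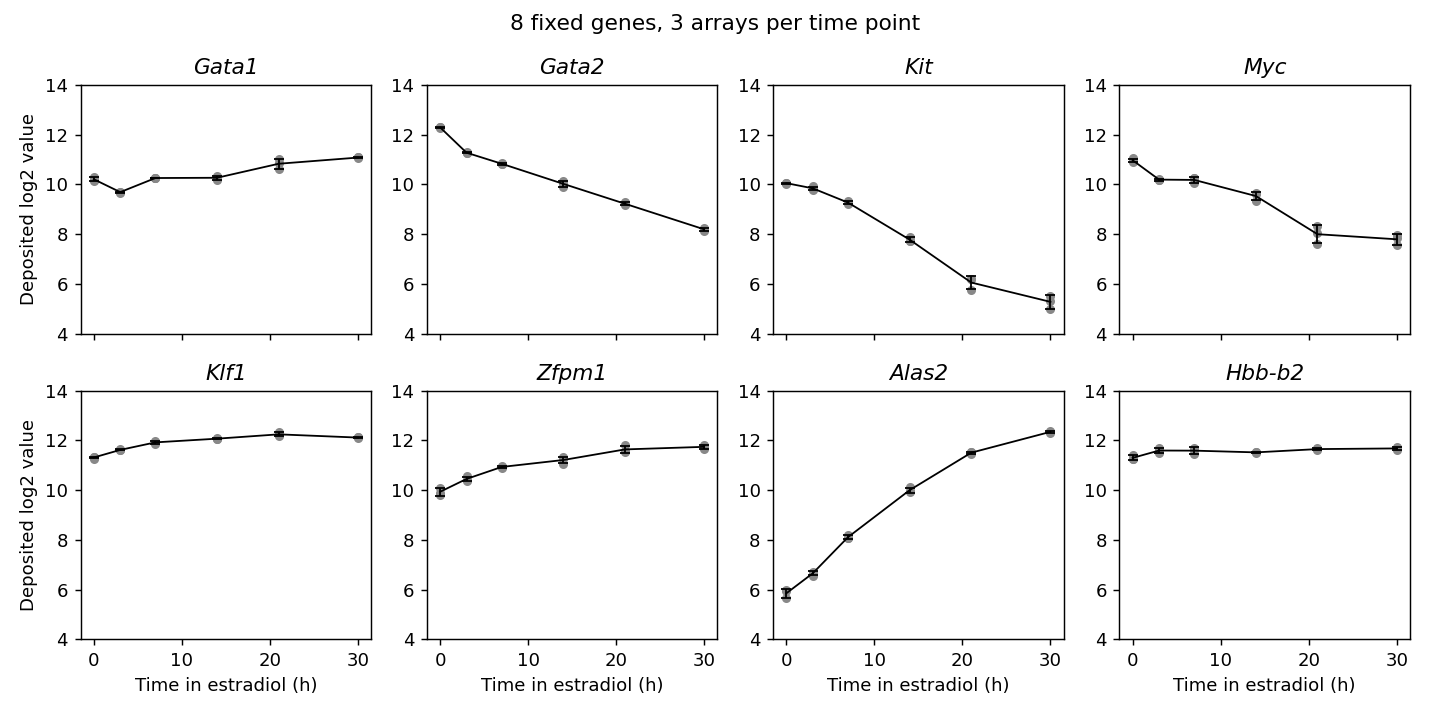
Deposited log2 values (y axis) of 8 genes against hours in estradiol (x axis). Grey points are arrays, lines join time point means and bars are SD over 3 arrays; Alas2 climbed from 5.85 to 12.34 while Gata2 fell from 12.29 to 8.19.

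At 3 h many genes had changed, most of them by a small amount. Ajuba, a LIM-domain adaptor, rose from 3.23 to 6.84 on the log2 scale, and Usp18, a brake on interferon signalling, from 3.23 to 6.24. Both started near the arrays' 40th percentile, 3.23 to 3.25 at 0 h, as did Gsdma (3.21), so their folds and rank are uncertain. Csf2rb and Csf2rb2, the shared and the mouse-specific beta chains of cytokine receptors, rose by 2.07 and 1.97. Mboat2, Gsdma, Efnb2 and Btn1a1 rose by 2.06, 2.02, 2.01 and 1.93. The largest falls included granzyme B (Gzmb, -2.76), the EGR corepressor Nab2 (-2.48), Plxdc1 (-2.35), the cholesterol exporter Abca1 (-2.11), Sall2 (-1.95) and the noncoding RNA Neat1 (-1.88). Socs3, a feedback inhibitor of cytokine signalling, gave -2.002 on the probe set used and -1.02 on another, both prone to cross-hybridise, and 0.16 (adjusted p = 0.516) on the remaining probe set, which at a mean of 3.37 lies near the arrays' low end and says little. Map1a gave -1.86 at 3 h, and its other probe set moved the opposite way at 30 h.

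Among fixed lists at 3 h, cholesterol synthesis genes fell, 11 of 18 (12 adjusted over the list alone) with 1 rise, and a median of -0.29 (camera adjusted p = 0.000352). With an estimated correlation the adjusted p = 0.251, and with control scaling the median was -0.20 and none (0) was called lower. G2-M and mitosis genes rose, 9 of 23 with no fall (0), and 11 rose adjusted over the list alone (adjusted p = 0.00364, and adjusted p = 0.361 with an estimated correlation). Control scaling called only 1, though their median went from 0.14 to 0.22. Heme synthesis enzymes and glycolysis genes, each with 4 genes up and 0 down, had adjusted p = 0.0440, and adjusted p = 0.361 with an estimated correlation, and control scaling called 2 genes up in each, with medians that went from 0.19 to 0.27 and from 0.07 to 0.16. None (0) of the 4 list calls at 3 h held with an estimated correlation. In total 1419 genes were higher and 1870 lower at 3 h than at 0 h, and 64 and 108 of them by at least 2-fold. Scaling on the hybridisation controls turned this to 484 higher and 307 lower.

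Between 3 h and 7 h, Tubb1, a beta tubulin of platelet and megakaryocyte lineage, rose 8.57-fold, and Dmtn, which binds spectrin to actin, rose 6.82-fold. Tmem184a and Tspoap1 rose by 2.44 and 2.33. The largest falls were the mast cell protease Cpa3 (-2.72), Rgs13 (-2.30, to a mean of 1.77 at the arrays' low end), Tespa1 (-2.28) and Cd200r4 (-2.10). Cholesterol synthesis genes turned up, 13 of 18 (16 adjusted over the list alone) with 0 falls, and a median of 0.34 (adjusted p = 6.10e-10, and adjusted p = 0.00489 with an estimated correlation), but none (0) was called with control scaling, where the median was 0.21. Erythroid transcription factors rose in 13 of 18 (adjusted p = 1.44e-09) and red cell membrane genes in 12 of 18 (adjusted p = 1.16e-10). Control scaling called only 1 and 5 of these, with medians of 0.24 in place of 0.37 and 0.42 in place of 0.55. In all, 1247 genes were higher and 655 lower than at 3 h. The lower count was 429 without 3 h replicate 2 and 404 without 3 h replicate 3, and control scaling gave 152 higher and 180 lower. Against 0 h, 1943 genes were higher and 2079 lower at 7 h, and the heme synthesis, iron and membrane lists were called higher (camera adjusted p = 2.55e-05, 0.00338 and 4.18e-07).

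Between 7 h and 14 h, Slc4a1, the band 3 anion exchanger of the red cell membrane, rose 7.57-fold, having fallen by 3 h. Slc52a3, the embryonic globin gene Hba-x and Fn3k rose by 2.46, 2.40 and 2.20. Vimentin (Vim), an intermediate filament, fell 9.46-fold, and Nebl, Erv3 and Spry4 changed by -2.51, -2.21 and -1.90. The G2-M list rose in 16 of 23 genes (18 adjusted over the list alone), with a median of 0.31 (adjusted p = 7.13e-09, and adjusted p = 0.0387 with an estimated correlation). At this step 1469 genes were higher and 1373 lower, against 1476 and 177 with control scaling. Compared with 0 h, 2828 genes were higher and 2888 lower at 14 h, and control scaling gave 2961 and 866. That scaling moved the median of all genes by between -0.21 and 0.27 on the log2 scale, depending on the comparison, so changes smaller than this are relative to the scale of the deposited values.

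Between 14 h and 21 h, ribosome biogenesis genes fell, 23 of 26 (24 adjusted over the list alone) with 0 rises, and a median of -0.55 (adjusted p = 6.06e-13, and adjusted p = 0.00384 with an estimated correlation). Glycolysis genes fell in 10 of 15 (adjusted p = 0.000222, and adjusted p = 0.0722 with an estimated correlation). Over the same step the 3' to 5' gap of control probe sets widened, from 1.87 to 2.15 for Actb, 1.19 to 1.52 for Gapdh, 2.03 to 2.43 for Tfrc and -0.06 to 0.63 for 18S ribosomal RNA. Such widening is a sign of shorter labelled RNA, and its effect on the genes called here was not tested. Slc4a1 rose a further 5.40-fold, Fam214b 3.72-fold, Tbx6 3.42-fold and Neat1 3.33-fold. Sowaha, Igf1r (the IGF1 receptor), the neurofilament gene Nefh and Slc26a1 changed by -2.72, -2.69, -2.58 and -2.52. This step had 1991 genes higher and 2231 lower, but 1069 and 1399 when only its own 6 arrays were fitted, and 149 and 1729 with control scaling. Against 0 h, 3990 genes were higher and 3637 lower at 21 h.

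From 21 h to 30 h, cell division genes fell together. All 23 measured G2-M and mitosis genes were lower at 30 h than at 21 h, with a median of -0.71 (camera adjusted p = 5.45e-15, and adjusted p = 0.0197 with an estimated correlation), and 27 of 29 DNA replication genes fell, with a median of -0.91 (adjusted p = 1.08e-18). With control scaling 13 of the 23 mitosis genes were called lower, with a median of -0.54. The embryonic globin gene Hbb-y rose 13.6-fold, Prex1 4.97-fold, the ATP-gated channel gene P2rx7 4.86-fold and the metallothionein gene Mt2 4.80-fold. At 30 h Mt2 still lay below its 0 h level (log2 -1.05), so its rise was a partial return. Car1, carbonic anhydrase 1, fell 6.58-fold and Dnah11 5.59-fold, while Cdca7l and Xkr5 fell from 6.25 and 5.77 to the arrays' low end (3.36 and 3.37). The step had 2286 genes higher and 2863 lower, of which 96 and 309 by at least 2-fold, and control scaling gave 1717 and 845.

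By 30 h red cell products were among the largest rises. Relative to 0 h, 4652 genes were higher and 4197 lower, together 69.5% of the 12727 tested, and 1165 and 1664 of them by at least 2-fold. Control scaling gave 5078 higher and 2671 lower. The largest rises were Tubb1 (291-fold, log2 8.18), the embryonic beta-like globin genes Hbb-bh1 (160-fold, 7.32) and Hbb-y (115-fold, 6.84), Dmtn (106-fold, 6.73), Alas2 and Slc4a1 (67.8-fold, 6.08). Slc38a5, an amino acid transporter, rose by 5.96, and Btn1a1, Ypel4, Slc52a3, Tmem184a and Evi5l by 5.70, 5.66, 5.35, 5.34 and 5.20. Several of these, such as Tubb1 at 2.43 and Hbb-y at 2.42, started near the low end of the array's signal, where folds are compressed or unstable.

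Globin, heme, iron and membrane lists were called higher. Of 5 measured globin chains 4 rose (adjusted p = 0.0111, and adjusted p = 0.0334 with an estimated correlation). Hbb-b2, an adult beta globin already at 11.29 at 0 h, rose by 0.38 on the probe set used. A dimmer probe set of Hbb-b2, prone to cross-hybridise, rose by 1.31 (limma adjusted p = 0.00215 with every probe set tested). Hba-a2 changed by 0.14 (adjusted p = 0.240). Probe sets shared by several globin genes, 4 in number, changed by 0.32 to 1.98. The one that rose by 1.98 started at 10.02, and the others at 12.26 to 12.99. Whether saturation of bright probe sets hid part of these rises was not tested. Heme synthesis enzymes rose in 7 of 8 (adjusted p = 0.00204), among them Ppox (1.97), Uros (1.45) and Alad (1.14), while Alas1, the form used outside red cells, fell by 0.66. Iron transport genes rose in 11 of 13 (adjusted p = 0.0111), among them the mitochondrial iron importer Slc25a37 (2.66), Fam210b (2.44) and Abcb10 (1.37), while transferrin receptor 2 (Tfr2) changed by -1.998. Red cell membrane genes rose in 14 of 18, or 15 adjusted over the list alone, with 0 falls and a median of 1.55 (adjusted p = 1.74e-06), including the spectrin gene Sptb (3.47) and Trim10 (2.20). Erythroid transcription factors rose in 14 of 18 and fell in 3 (adjusted p = 0.0111), led by Mxd1 (2.59), Zfpm1, Klf3 (1.16) and Mxi1 (1.06).

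Progenitor genes went the other way. Of 14 measured, 7 fell and 2 rose (3 adjusted over the list alone), with a median of -0.25 (adjusted p = 0.0143, and adjusted p = 0.130 with an estimated correlation). Control scaling gave a median of -0.05, with 6 down and 4 up. Lyl1, a helix-loop-helix factor of early blood cells, changed by -5.85, Kit by -4.77, Myb by -4.62 and Gata2 by -4.10. Outside the lists, large falls included Car1 (75.7-fold), Vim (57.3-fold), Nefh and Klf10 (44.2-fold). Erv3, Sowaha, Iqgap2, Marcksl1, Cdca7l and Armcx4 fell to means of 2.63 to 3.45, near or below the arrays' 40th percentile at 30 h (3.28 to 3.35), so their folds and their order are uncertain.

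Markers of other blood lineages moved in both directions. Of 9 mast cell and basophil genes, 5 fell and 1 rose. Camera did not call the list at 30 h (median -0.94, adjusted p = 0.0866), except with the 60th-percentile filter (median -2.87, adjusted p = 0.0144) and with control scaling (adjusted p = 0.00518). Fry called it at 30 h (adjusted p = 1.24e-11). By camera it was called lower at 7, 14 and 21 h (adjusted p = 0.0150, 0.00936 and 0.0113), and at 7 h the call had adjusted p = 0.0579 with an estimated correlation. Cpa3 fell by 5.42, Ms4a2 (the beta chain of the IgE receptor) by 3.43, Gzmb by 2.87 and Hdc (histidine decarboxylase) by 1.14, and the 30 h means of Cpa3, Ms4a2 and Gzmb (2.66, 2.14 and 3.41) lay near or below the arrays' 40th percentile. Of 10 megakaryocyte genes, 3 rose and 4 fell (adjusted p = 0.795). Tubb1 and Itgb3 (2.05) rose, and the platelet genes Gp5 and Pf4 fell (-3.99 and -2.34). The list's median turned from -0.14 to 0.05 with control scaling. Granulocyte and macrophage genes (4 rose and 2 fell of 9, adjusted p = 0.795) and lymphoid genes (2 rose and 0 fell of 7, adjusted p = 0.695) were not called by camera. Fry called the lymphoid list (adjusted p = 0.00857), and called the megakaryocyte list higher (adjusted p = 1.32e-06). Cd68 fell by 0.79, Ms4a3 by 0.57, and Csf1r (0.64), S100a9 (0.56), Cd8a (0.51) and Cd4 (0.44) rose, all at means under 6. The calls of Ms4a3 and S100a9 were lost when certain arrays were left out, with adjusted p = 0.0707 without 30 h replicate 1 and 0.0917 without 0 h replicate 2. Ighm (-0.29, adjusted p = 0.119) and Pax5 (-0.30, adjusted p = 0.184) were not called, but were without 30 h replicate 3 (-0.41 and -0.51, adjusted p = 0.0461 and 0.0242).

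Ribosome biogenesis genes fell in 25 of 26, with a median of -1.88 (camera adjusted p = 2.66e-11, and adjusted p = 0.00692 with an estimated correlation), led by Utp20 (-2.82), Nolc1 (-2.82), Nop16 (-2.70) and Nop2 (-2.63). The control probe sets for 18S ribosomal RNA, outside the gene counts, were lower too (3' -0.94, middle -1.18, 5' -2.36). DNA replication and G1-S genes fell in 25 of 29 and rose in 3 (median -0.99, adjusted p = 6.24e-07), including Cdk6 (-3.05), Mcm10 (-1.87), Tyms (-1.77) and Tk1 (-1.76). Inhibitors of cyclin-dependent kinases rose in 4 of 4 (adjusted p = 0.00952), with Cdkn2c at 1.75, Cdkn1b at 1.59, Cdkn2d at 1.36 and Cdkn1a at 0.74. The mitosis list had been higher at 14 h and 21 h, with 19 of 23 genes up at each (20 at 14 h adjusted over the list alone). At 14 h the adjusted p = 5.88e-08, and 0.0423 with an estimated correlation. At 21 h the call had adjusted p = 0.0912 with an estimated correlation. At 30 h it was split, 9 up (10 adjusted over the list alone) and 11 down (camera adjusted p = 0.690). Fry, which does not compare a list with other genes, called it at 30 h (adjusted p = 0.00481). Its median turned from -0.07 to 0.13 with control scaling. Cdc25b was up by 2.46, and Bub1b, Aurkb and Cdk1 were down by 1.30, 1.16 and 1.06.

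**Figure D2:**
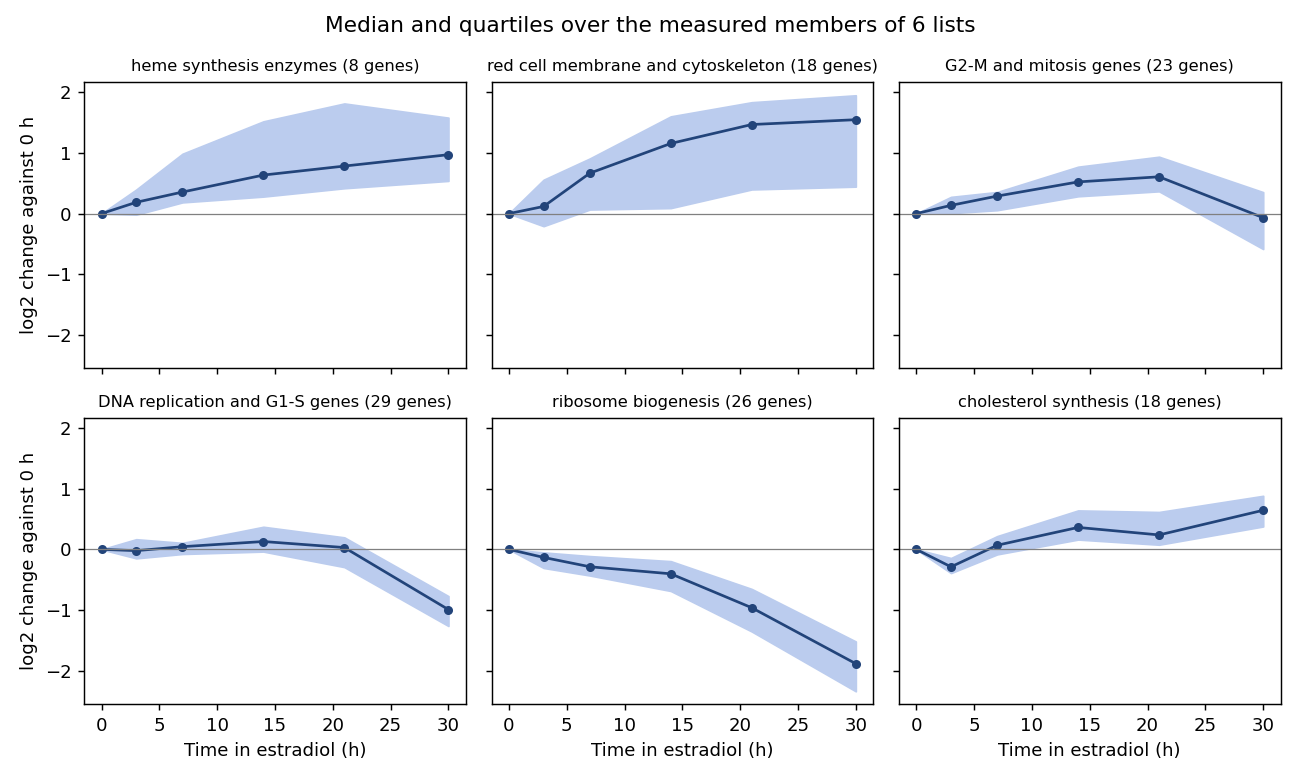
Median log2 change against 0 h (line) and its quartiles (band) over the members of 6 lists, by hours in estradiol (x axis). Mitosis genes reached a median of 0.61 at 21 h and returned to -0.07 at 30 h, while ribosome biogenesis genes reached -1.88.

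Autophagy genes rose in 16 of 22 and fell in 2 (adjusted p = 0.000960, and adjusted p = 0.0334 with an estimated correlation), including Map1lc3a (2.70), Wipi1 (2.58), Atg4d (2.19) and Gabarap (1.55). Cholesterol synthesis genes rose in 15 of 18 and fell in 1 (adjusted p = 0.00204, and adjusted p = 0.0722 with an estimated correlation), led by Fdft1 (1.31), Ebp (1.22), Msmo1 (1.20) and Nsdhl (0.90). Reference genes often used for normalization were called lower, 7 of 11 with 1 rise (adjusted p = 0.0354, and adjusted p = 0.0779 with an estimated correlation). The call was also lost with the 60th-percentile filter (adjusted p = 0.103), the mean of each gene's probe sets (0.0602) and control scaling (0.126, median -0.25 in place of -0.45). Among them were Gusb at -2.005, Hprt at -0.96, Pgk1 at -0.94 and Tbp at -0.93.

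The other lists were not called at 30 h by camera. Fry, which does not compare a list with other genes, called most of those in this paragraph. These were the BCL2 family, glycolysis, antioxidant, cytokine, interferon, unfolded protein and estrogen receptor target lists (adjusted p = 7.01e-12 to 0.00641). In the BCL2 family (adjusted p = 0.186), 10 of 13 genes rose, with the survival gene Bcl2l1 up by 2.45 and Bnip3 by 1.49, and Bcl2 and Bid down by 2.33 and 2.11. Glycolysis genes (adjusted p = 0.531) had 6 up and 6 down of 15 and a median of -0.03 that became 0.17 with control scaling, with Hk1 (1.37) and Pfkm (1.29) up and Hk2 and Ldha down by 2.51 and 2.36. Antioxidant genes had 9 up of 14 (adjusted p = 0.139), with Hmox1 at 1.79, Cat at 1.01, Srxn1 at 0.85 and Sod2 at -1.04. Cytokine signalling genes (adjusted p = 0.381) included Csf2rb, 14.4-fold higher, Cish (1.56), Osm (-2.21) and Stat5a (-1.35). Interferon-stimulated genes (adjusted p = 0.469) included Irf7 (1.90), Usp18 (1.77), Irf9 (1.497) and Ifih1 (-1.02). Immediate early genes (adjusted p = 0.875) included Zfp36 (1.95), Jun (1.77), Ier2 (-2.44) and Ier3 (-1.84). Unfolded protein response genes (adjusted p = 0.890) included Ddit3 (2.52), Dnajb9 (1.46), Pdia4 (-1.40) and Psat1 (-1.11). Estrogen receptor target genes, listed because the cells received estradiol, were not called either (adjusted p = 0.614), with 3 up and 1 down of 7, among them Ctsd (1.04), Tff1 (0.71), Esr1 (0.42) and Nrip1 (-0.87). The calls of Tff1 and Esr1 were lost without 0 h replicate 1 and without 0 h replicate 2 (adjusted p = 0.0522 and 0.0751).

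Over all times 9454 of 12727 genes changed by the F test. Of the 4652 genes higher at 30 h, 1056 were already higher at 3 h, and of the 4197 lower at 30 h, 1196 were already lower at 3 h. Independent lists of these sizes would share 518.7 and 616.7 genes, a value that leaves out the shared 0 h arrays. Genes called the opposite way at 3 h and 30 h numbered 402 that fell and then lay higher and 176 that rose and then lay lower. Changes at 3 h and 30 h correlated at r = 0.465 across genes, and unchanged simulated groups sharing the 0 h arrays gave 0.498. The 2 changes had the same sign in 66.91% of genes, against 66.74% simulated. Both simulated values follow by construction from noise around shared 0 h arrays, so they are no baseline for data with real changes. The covariance was 0.152 against 0.00711 simulated, so the simulated noise of the shared arrays was small beside it. Genes called at both times, in either direction, numbered 2830. The simulation without effects gave 0.05, but it is near 0 by construction and says nothing about the overlap of real changes. Part of the overlap beyond that of independent lists may come from the shared 0 h arrays. How much was not tested, because splitting 3 control arrays leaves fewer than 2 for 1 of the comparisons.

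**Figure D3:**
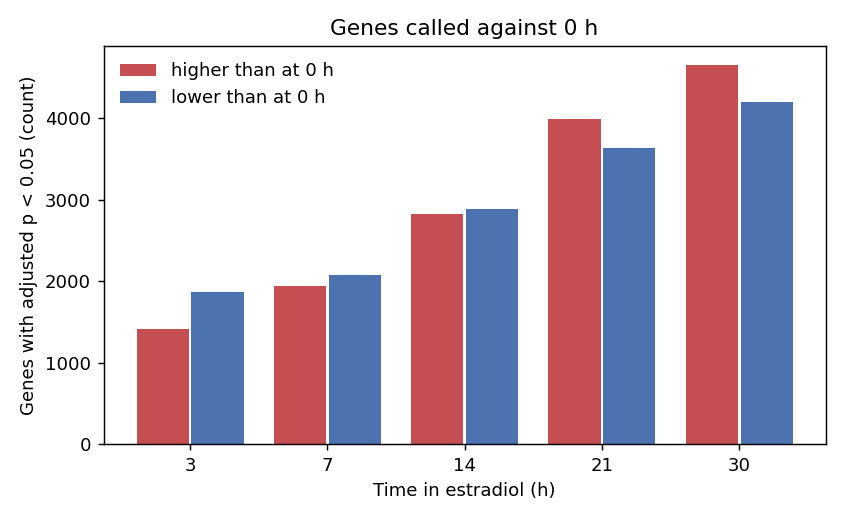
Number of genes (y axis, from 0) higher (red) or lower (blue) than at 0 h at an adjusted p under 0.05, by hours in estradiol (x axis). Higher genes rose from 1419 at 3 h to 4652 at 30 h, and lower genes from 1870 to 4197.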

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

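The tests on the 18S, mast cell and mitosis patterns below were chosen after the results were seen. So was the cholesterol synthesis list for the comparison of 30 h with 3 h. The regroupings of arrays were planned before their results were seen.

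The 18S ribosomal RNA control probe sets, which no comparison of genes uses, were lower at 30 h than at 0 h, with -0.9377 for the 3' set, -1.179 for the middle and -2.3564 for the 5' set. Scaling between arrays is argued against by the hybridisation controls, whose median change was -0.2364. Shorter labelled RNA as the whole cause would leave the 3' set unchanged only if labelling began at the 3' end of 18S. That was not checked, so the fall of the 3' set (-0.9377) cannot decide. The 3' to 5' gap of Actb, Gapdh and Tfrc also widened, by a median of 0.3869. Most of it came between 14 h and 21 h (median 0.3235, with SEs of 0.16 to 0.17). Shorter target may therefore lie behind the greater loss at the 5' end. Ribosome biogenesis genes had a median of -1.8824, but this moved with time as everything else did, so less ribosome production and other effects of time cannot be told apart and it remains a hypothesis.

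Of 9 mast cell and basophil genes 5 were lower and 1 higher at 30 h than at 0 h. Camera did not call the list as a whole (adjusted p = 0.0866) except with the stricter filter (0.0144) and control scaling (0.00518). Fry, which does not compare a list with other genes, called it (adjusted p = 1.24e-11). Loss of a mast-like cell fraction as the whole cause would lower these genes by a common factor, but at 3 h their changes spanned 2.9957 on the log2 scale, from -2.76 for Gzmb to 0.24 for Hdc. Gzmb lay near the arrays' floor at 3 h (3.53), and most of the span comes from it. Cpa3 (-0.92, SE 0.24) and Hdc (SE 0.18) also lay apart, but the change of Hdc was not called (limma adjusted p = 0.379 with every probe set tested). Without Gzmb this smaller gap, between genes picked as the ends, decides little. A common factor also holds only for genes confined to the lost fraction, which was not checked. Loss beside direct regulation stays open. Other scalings moved the median gene at 30 h versus 0 h by at most 0.197. Repression by restored GATA1 activity is a candidate explanation that the design, without cells kept from estradiol, did not test.

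Mitosis genes were called higher than at 0 h from 3 h to 21 h, and lower at 30 h than at 21 h. Against 0 h, camera with an estimated correlation kept the call at 14 h (adjusted p = 0.0423), but not those at 3, 7 and 21 h (adjusted p = 0.361, 0.181 and 0.0912). Between neighbouring times it kept the rise from 7 h to 14 h and the fall from 21 h to 30 h (adjusted p = 0.0197). Arrays at 21 h out of line are argued against by the 19 of 23 genes already higher at 14 h. Shorter labelled RNA as the whole cause is argued against by the step from 14 h to 21 h. The 18S 3' to 5' gap widened by 0.687 (SE 0.088) there, more than from 21 h to 30 h. Yet the list had a median change of 0.084 (-0.123 with control scaling). The gaps of Actb, Gapdh and Tfrc widened by 0.27, 0.32 and 0.40, with SEs of 0.16 to 0.17. Whether they widened more than from 21 h to 30 h is uncertain with these SEs, so the argument rests on 18S. A part played by shorter RNA stays open, since the mRNA gaps changed by a median of 0.0013 from 21 h to 30 h with SEs of 0.105 to 0.180, and the 18S gap widened by 0.277 (SE 0.0975). A change in cell division was not tested and stays open too.

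Cholesterol synthesis genes were called lower at 3 h and higher at 30 h by camera, but neither call held with an estimated correlation (adjusted p = 0.251 and 0.0722), and control scaling left 0 genes called lower at 3 h. The difference between 30 h and 3 h had a median of 0.8722 (camera adjusted p = 1.51e-05), and was also called with an estimated correlation (adjusted p = 0.0257) and with control scaling (adjusted p = 0.000163). Because the list was picked for its opposite calls, this difference in part restates them and is no independent support. Named genes called in opposite directions at 3 h and 30 h are listed with their change from 3 h to 30 h, a difference that follows from those calls and adds no test of its own. Erythroid and membrane genes Slc4a1 (7.3316), Klf3 (1.6944) and Gata1 (1.3898) fell and then rose. So did Fam214b (5.0284), Neat1 (4.5389), Hmox1 (2.9913), Zfp36 (2.7581), P2rx7 (2.6954), Bcl2l1 (2.6729), Cish (2.2469), Fdft1 (1.8285), Cdkn2d (1.6713), Srxn1 (1.648) and Ctsd (1.4061). Genes that rose and then fell were Slc26a1 (-4.5876), Hk2 (-3.4012), Bcl2 (-2.7831), Aurkb (-1.3136) and Ms4a3 (-1.21). Some changes at 3 h were small: Aurkb 0.15 (limma adjusted p = 0.0485), Bcl2l1 -0.23 (0.0335), Cdkn2d -0.31 (0.0390) and Bcl2 0.45 (0.0432). At 3 h Aurkb was not called with every probe set tested (limma adjusted p = 0.0717), nor Gata1 with control scaling (0.181). That scaling called 0 genes lower at 3 h in the cholesterol synthesis, cyclin-dependent kinase inhibitor and estrogen receptor target lists. The falls of Fdft1, Cdkn2d and Ctsd were therefore lost as well. Most of the other genes named here were not followed singly with that scaling at 3 h.

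Probe sets outside the gene counts changed too. Of those with no gene listed, 1380 were higher and 1312 lower at 30 h than at 0 h, and of those listed with several genes, 201 and 239.

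Regrouping the arrays gave the following. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and in each of the 9 comparisons 1 split, the real one, gave the largest count. The real counts from the 6 arrays alone were 3652 at 3 h, 3816 at 7 h, 5073 at 14 h, 6735 at 21 h and 8679 at 30 h against 0 h, and 2435, 2112, 2468 and 3896 for the 4 steps in order of time. The highest of the other splits called 0 genes in each comparison. For the F test, 1 of 100 groupings, the real one, gave as many as 9454 genes, and the highest other gave 3452. A random assignment of these arrays to times was therefore unlikely to give as many. Regrouping cannot address differences between cultures or batches that coincide with time.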

How the results depend on the processing

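Counts that moved and values that turned with other choices are given here, and the cause was not tested. Scaling on the hybridisation controls, chosen after seeing the data, gave 484 genes higher and 307 lower at 3 h, 590 and 691 at 7 h, 2961 and 866 at 14 h, 2576 and 2383 at 21 h and 5078 and 2671 at 30 h. From 3 h to 7 h it gave 152 and 180, from 7 h to 14 h 1476 and 177, from 14 h to 21 h 149 and 1729 and from 21 h to 30 h 1717 and 845. It rests on 9 control probe sets, whose own spread it carries over. The immediate early gene list, not called in either, had a median of 0.6564 and changed test direction. Asking for at least 2-fold left 64 and 108 at 3 h, 206 and 168 at 7 h, 403 and 476 at 14 h, 778 and 1038 at 21 h and 1165 and 1664 at 30 h, and 63 and 38, 48 and 92, 45 and 170, and 96 and 309 for the steps in order of time. Fitting only the times compared gave 1069 higher and 1399 lower from 14 h to 21 h. With an estimated correlation camera called 7 lists higher and 2 lower at 30 h, and fry called 16 and 7. Test direction turned for lists not called by camera: megakaryocyte markers with the stricter filter (-0.1959), glycolysis (0.0728) and estrogen receptor targets (-0.108) with every probe set tested. Fry called the megakaryocyte list higher at 30 h (adjusted p = 1.324e-06), where camera's direction was lower. The median of that list under fry was the unchanged -0.1445. Ighm at 30 h was 0.1151 with the mean of its probe sets, and Socs3 at 3 h was 0.1604 without cross-hybridising probe sets. The call of the reference genes at 30 h was lost with the stricter filter (adjusted p = 0.1031), the mean of probe sets (0.06021) and control scaling (0.1262). The mast cell list was called at 30 h by camera with the stricter filter (-2.8741, adjusted p = 0.01439) and control scaling (-0.7423, 0.005184), and by fry (adjusted p = 1.235e-11). No other pseudocount was tried, because the values were already on a log scale.

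Leaving out 1 array at a time gave 404 (without 3 h replicate 3) to 775 (without 21 h replicate 3) genes lower at 7 h than at 3 h, 1070 to 1527 higher and 1311 to 2069 lower at 3 h than at 0 h, 4204 to 4719 higher and 4009 to 4253 lower at 30 h than at 0 h, and 9046 to 9502 genes changed over time. With the replicate number as a replicate block, 4669 genes were higher and 4186 lower at 30 h. Across 45 same-numbered pairs of arrays the mean correlation after removing time was 0.0122, with 7 above 0.1, so the numbers did not pair arrays.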

Other observations

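Other gene families, chosen by symbol after the data were seen, add to the picture at 30 h. Subunits of the V-ATPase, the proton pump of lysosomes, rose in 14 of 17 with 0 falls and a median of 0.79 (camera adjusted p = 8.58e-06, and adjusted p = 0.0430 with an estimated correlation), the same direction under each of the 4 scalings. Mitochondrial ribosomal protein genes fell in 47 of 75 and rose in 3, with a median of -0.62 (adjusted p = 6.75e-07, and adjusted p = 0.381 with an estimated correlation). Translation initiation factors fell in 27 of 46 (adjusted p = 0.00792, and adjusted p = 0.0578 with an estimated correlation) and aminoacyl-tRNA synthetases in 12 of 19 (adjusted p = 0.0289, and adjusted p = 0.439 with an estimated correlation). The initiation factor set, matched by symbol, takes in Eif2ak1 and Eif2ak2, which encode eIF2 kinases and not initiation factors. Control scaling left 14 initiation factors and 4 synthetases lower (5 and 3 higher), with medians of -0.14 in place of -0.33 and -0.18 in place of -0.37.

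Not called were proteasome subunits (17 of 37 fell and 9 rose, adjusted p = 0.170), ubiquitin-conjugating enzymes (14 of 30 rose and 5 fell, adjusted p = 0.170), respiratory complex I subunits (15 of 34 fell and 10 rose, adjusted p = 0.550), CCT chaperonin subunits (6 of 9 fell and 2 rose, adjusted p = 0.0838) and Hox genes (3 of 13 rose and 3 fell, adjusted p = 0.975). Control scaling turned the medians of complex I (-0.08 to 0.12) and the proteasome (-0.10 to 0.10) positive.

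Cytosolic ribosomal protein genes had a median of -0.11 (23 of 46 fell and 1 rose, adjusted p = 0.0289, and adjusted p = 0.445 with an estimated correlation), and 0.09 with control scaling, against -1.88 for ribosome biogenesis genes. Most are bright: 34 had 0 h means above all biogenesis genes, with a median change of -0.08, where saturation could hide a fall. The 8 within the biogenesis list's range of 0 h means had a median of -0.98, from -3.94 to 0.04. Their difference from the biogenesis list, 0.9048 in a test chosen after the medians were seen, is too uncertain with 8 genes to decide. For these genes a fall to the same extent stays open. Among the 34 brighter genes the lowest change was -0.35, which argues against an equal fall there unless saturation hid it.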
